A study of Mus musculus with 4 samples.

How the data were processed

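RNA of cultured mouse oligodendrocytes from 2 groups, wild type (WT) and Ninj2-deficient, was sequenced in 2 libraries per group. Groups and replicate numbers were taken from the sample titles. Per the labels' protocols, the cells came from the cortices of pups aged 3 to 8 postnatal days, were selected by immunopanning as O4-positive and GalC-negative cells, and were harvested on day 2 of differentiation. The labels do not say how the deficiency was made, which exons it affects, or whether the libraries of a group came from separate cultures or litters, so the p-values below measure only the spread between these libraries, which may be technical.

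Per the submitters' processing notes, reads were aligned to mm10 with HISAT2 2.0.5, and featureCounts 1.5.0-p3 and StringTie 1.3.3b were used for gene counts. The authors deposited FPKM, fragments scaled to gene length and to the library total, for 54532 genes with their lengths and coordinates. The gene lengths that the authors deposited beside the FPKM are in bases, another kind of value that was used here only to recover fragments. How FPKM was scaled, how reads with several alignments were treated and whether counting used strand are not given in the sources used here. Of the gene identifiers, 54409 are in GENCODE M21 (GRCm38, the assembly also called mm10), and 98.3% of these have identical coordinates there.

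Multiplied by gene length, every FPKM above 0 was a whole multiple of 1 step per library (100% of values within 0.01 of a whole number), so the number of fragments behind each value could be recovered. The recovered fragments numbered 18451885 and 19518466 in the WT libraries and 18525337 and 20323459 in the Ninj2-deficient libraries. The library total that the FPKM imply was 0.972 and 0.969 times the recovered sum in WT and 1.04 times in both Ninj2-deficient libraries, so the authors' FPKM carry a scaling between groups that is not stated. The FPKM were used as deposited, and other scalings were run as alternatives. Intervals on fragments cover counting error only.

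The test was limma 3.58.1 in R 4.3.3 with an intensity trend (limma-trend) on log2(FPKM + 1), with genotype as the only term, over genes with a mean FPKM of at least 1 over the 4 libraries. Ninj2 was to be kept whatever its mean. This left 13120 genes. Adjusted p-values are Benjamini-Hochberg values over these genes, and a gene was called at an adjusted p under 0.05. Fold changes on the log2(FPKM + 1) scale understate the change of low genes, and plain folds are ratios of mean FPKM. The submitters used DESeq2 on counts with a fold over 2 and p under 0.05, per the series' design text. Here the same thresholds were applied to the limma fit, with the unadjusted p. With 2 libraries against 2, an exact permutation test of a single gene cannot give a p below 0.333, so each p rests on the spread that limma shares across genes.

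Before the data were examined, 25 gene lists were fixed, 17 of pathways or cell states and 8 of cell type markers. The 22 lists with at least 5 tested members were tested with limma's camera at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry were alternatives. With an estimated correlation no list passed, with fry 18 did. With the estimated correlation, camera's p-values also rest on the few degrees of freedom that 4 libraries leave. A lost call there does not by itself show correlated members. The estimated correlation was -0.02 for the myelin list, -0.029 for the cell cycle list and 0.354 for the mitochondrially encoded list. The genes named in the text were chosen by a rule fixed at the same time. It takes Ninj2, the 12 called genes with the largest rise and the 12 with the largest fall whose groups do not overlap (leaving out Gm numbers, Rik clones, pseudogenes and unnamed loci), and up to 4 called members of each list with the largest change, or the 2 highest members where none was called. Other genes that are named were chosen after their values were seen.

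Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter, a mean FPKM of at least 5, median ratio scaling, rescaling to equal sums (TPM), quantile normalization, limma without a trend, a replicate block, leaving out each library, and protein-coding genes only. Another 4 were chosen after seeing the data: removal of a trend with GC content (loess, span 0.5, on the longest GENCODE M21 transcript, known for 99.9% of tested genes), limma's voom on the recovered fragments, scaling to the recovered totals, and at least 50 recovered fragments per gene. Other tools were Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

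The steps were tested on simulated data: fragments for the 13120 tested genes of this comparison were drawn at the measured means and library totals, with 50 genes changed at each of 4 fold sizes. All genes were given 1 dispersion, 0.000722, estimated between the libraries within each group. The counts that follow therefore hold for replicates as alike as these, not for more variable cultures. Only 200 genes and a planted list were changed, against 5657 genes called in the data. The Benjamini-Hochberg cutoff therefore differs, and the rates of recovery and of false calls do not carry over to the data. The limma step recovered 17 of 50 genes changed 1.25 times, 39 changed 1.5 times, 48 changed 2 times and 49 changed 4 times, with 15 false calls among 12900 unchanged genes. In the same simulation, camera with the preset correlation gave a p of 3.21e-40 for a planted list of 20 genes raised 1.5 times, and 0.0192 with an estimated correlation. Of 100 lists of unchanged genes, 4 had a p under 0.05. The simulated genes were drawn independently, so these lists cannot show how often camera with the preset correlation passes lists of correlated genes.

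Before averaging, the libraries of a group were compared by a chi-square of their recovered fragments. It was 2.16 per gene between the WT libraries and 2.28 between the Ninj2-deficient libraries, more than sampling noise gives, so neither pair holds the same reads deposited again. Repeated sequencing of the same library is not excluded, since technical differences also raise the chi-square. Of the 102 genes that the rule names, 17 overlap another tested gene in the annotation. Among them are Elovl1 (Cdc20), S100b (Dip2a), Nkx6-2 (Inpp5a), Tmem163 (Mgat5), Col4a1 with Col4a2, and Sarnp (Dnajc14 and Ormdl2), and their values are uncertain as far as reads were shared. The same holds for genes with near-identical copies, such as Lyz2, Gapdh and several mitochondrially encoded genes.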

Results

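Gene expression was measured by RNA sequencing in primary mouse oligodendrocyte cultures on day 2 of differentiation, in 2 WT and 2 Ninj2-deficient libraries. Between 18451885 and 20323459 fragments per library could be assigned to genes, and between 23265 and 24370 genes had at least 1 fragment. All means below are FPKM ± SD over n = 2 libraries per group, and fold changes and adjusted p-values come from limma. The first principal component took 80.3% of the variance over 13120 tested genes and separated the groups. Mitochondrially encoded genes took 1.69% and 1.62% of fragments in WT and 1.94% and 1.97% in the Ninj2-deficient libraries.

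Ninj2 (ENSMUSG00000041377, chromosome 6, 120093350 to 120200339, mm10) encodes ninjurin 2, a membrane protein of the ninjurin family. Its mRNA was lower, but not lost, in the libraries labelled Ninj2-deficient. It stood at 2.56 and 2.31 FPKM in the WT libraries and at 1.66 and 1.37 FPKM in the Ninj2-deficient libraries, a log2 fold change of -0.45 ± 0.096 (SE, adjusted p = 0.0194). These values rest on 84 fragments in WT and 57 in the Ninj2-deficient group, a ratio of 0.62 with an exact 95% interval from 0.435 to 0.878. The call was lost without WT library 1 (adjusted p = 0.0869), WT library 2 (0.0581) or Ninj2-deficient library 2 (0.0767), with no filter (0.0738) and with voom (0.0621). Its relative Ninj1, which encodes a protein of plasma membrane rupture, also fell, from 25.3 ± 0.72 to 17 ± 1.304 FPKM (adjusted p = 0.00268).

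The only comparison that the design holds asks which mRNAs differ between Ninj2-deficient and WT cultures. Myelin genes were far lower and cell cycle genes higher in the Ninj2-deficient libraries. Mbp, which encodes myelin basic protein, stood at 875 ± 12.5 FPKM in WT and 79.2 ± 0.785 FPKM in the Ninj2-deficient libraries (11.0-fold lower, log2 fold change -3.45 ± 0.022 SE, adjusted p = 3.01e-06). Mki67, a marker of dividing cells, rose from 3.41 ± 0.241 to 17.1 ± 1.52 FPKM (5.01-fold, log2 fold change 2.03 ± 0.077 SE, adjusted p = 0.000164). Of 13120 genes tested, 5657 were called, 2467 higher and 3190 lower, and 356 passed the submitters' thresholds, 124 higher and 232 lower. The groups did not overlap for 74.0% of the tested genes, against 33.3% by chance.

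Higher genes made up 43.6% of the calls with the FPKM as deposited, but 65.7% after rescaling to TPM, 63.8% after scaling to the recovered totals and 55.4% after quantile normalization, so the direction of small changes depends on the scaling. The total of genes past the submitters' thresholds ran from 219 with a mean FPKM of at least 5 to 653 with voom.

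**Figure D1:**
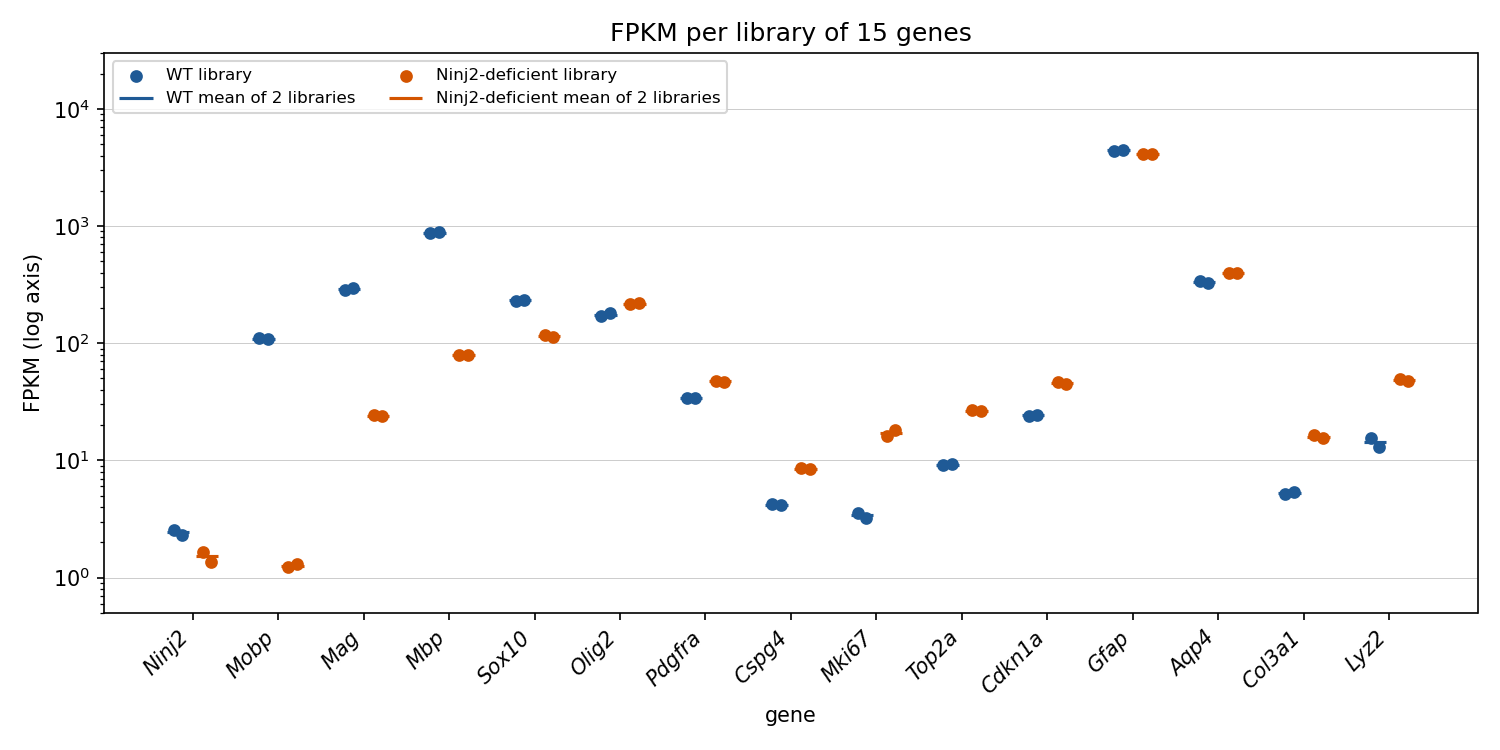
FPKM per library (log axis) of 15 genes in WT (blue) and Ninj2-deficient (orange) cultures, with points for single libraries and lines for means of n = 2. Mobp, Mag and Mbp lie lower and Mki67, Top2a, Col3a1 and Lyz2 higher in both Ninj2-deficient libraries, while Gfap is the highest of the 15 in all 4 libraries.

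Of 22 tested genes of the myelin and mature oligodendrocyte list, 20 fell, none rose and 2 (Trf and Ndrg1) were not called (21 fell adjusted over the list alone). The list's median log2 fold change was -1.86 (camera adjusted p = 8.9e-15, and adjusted p = 0.137 with an estimated correlation). The largest fall was that of Mobp, a myelin-associated basic protein, from 109 ± 1.67 to 1.27 ± 0.0408 FPKM (85.9-fold). Mag, an adhesion molecule of the myelin membrane next to the axon, fell 12.1-fold, from 291 ± 7.59 to 24.1 ± 0.278 FPKM, and Mal, a membrane protein of myelin, fell 16.5-fold. Other abundant mRNAs of the list fell less. Cldn11 fell 3.498-fold to 224 ± 1.09 FPKM and Cnp fell 3.03-fold to 249 ± 2.95 FPKM. Also among the 12 largest falls were S1pr5, a sphingosine 1-phosphate receptor of oligodendrocytes (42.4-fold), Tmem125 (37.1-fold), Kndc1 (24.3-fold), Hapln2 (21.95-fold), Tmem151a (13.5-fold), Tppp, a tubulin-binding protein (10.1-fold), and Ermn, a cytoskeletal protein of oligodendrocytes (72.6-fold, with 16 fragments left in the Ninj2-deficient group).

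Genes of committed and premyelinating oligodendrocytes fell by less. Of 15 tested, 14 fell and Kif21a was not called (14 fell adjusted over the list alone), with a median of -0.62 (camera adjusted p = 2.2e-07, and adjusted p = 0.148 with an estimated correlation). Sirt2 fell from 333 ± 7.51 to 127 ± 1.26 FPKM, Tmem163 from 25.9 ± 2.12 to 8.87 ± 0.176 FPKM, Rras2 from 10.1 ± 0.597 to 4.24 ± 0.258 FPKM and Frmd4a from 11.8 ± 0.0683 to 5.93 ± 0.176 FPKM. Precursor genes moved both ways. Of 20 tested, 10 rose, 7 fell and 3 were not called (12 and 7 adjusted over the list alone), with a median of 0.14, and the list did not pass (camera adjusted p = 0.119). It passed after quantile normalization (median 0.20, adjusted p = 0.016) and with fry (adjusted p = 0.000742). The proteoglycan NG2, encoded by Cspg4, rose in mRNA from 4.19 ± 0.0236 to 8.47 ± 0.103 FPKM, Ptprz1 from 95.8 ± 2.31 to 149 ± 0.544 FPKM, the PDGF receptor gene Pdgfra from 34.1 ± 0.437 to 47.3 ± 0.399 FPKM and Vcan from 3.96 ± 0.423 to 5.65 ± 0.08 FPKM. Pdgfra is also a member of the fibroblast list. Among the 7 that fell were Matn4, from 2.33 ± 0.0693 to 1.52 ± 0.139 FPKM, and C1ql1, from 31.1 ± 4.01 to 24.3 ± 0.212 FPKM. Tnr fell from 63.2 ± 1.86 to 52.6 ± 0.26 FPKM.

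Among the transcription factors of the lineage, 10 of 16 fell, 3 rose and 3 were not called (10 and 4 adjusted over the list alone), with a median of -0.54 (camera adjusted p = 0.00885, and adjusted p = 0.185 with an estimated correlation). Nkx6-2 fell from 46.8 ± 2.85 to 7.21 ± 0.486 FPKM, Myrf, the regulator that turns on myelin genes, from 69.5 ± 0.672 to 20.9 ± 0.286 FPKM, Zfp536 from 4.17 ± 0.246 to 0.886 ± 0.0955 FPKM and Sox10, a factor of the whole lineage, from 232 ± 3.02 to 115 ± 2.79 FPKM. Olig2, also expressed throughout the lineage, rose from 175 ± 6.72 to 218 ± 3.18 FPKM. The list did not pass over genes with a mean FPKM of at least 5 (adjusted p = 0.148).

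Lipid synthesis genes were lower in part. Of 20 fatty acid and sphingolipid genes, 16 fell, Srebf1 rose and 3 were not called (16 and 1 adjusted over the list alone), with a median of -0.21 (camera adjusted p = 5.31e-05, and adjusted p = 0.148 with an estimated correlation). Gal3st1, the sulfotransferase that makes sulfatide, fell from 54.4 ± 0.671 to 16.5 ± 0.922 FPKM, Elovl7 from 24.7 ± 0.331 to 9.90 ± 0.0306 FPKM, Acsl1 from 4.32 ± 0.0101 to 1.5 ± 0.164 FPKM and Elovl1 from 32.7 ± 0.167 to 17.4 ± 0.243 FPKM. Of 22 cholesterol synthesis genes, 12 fell, 3 rose and 7 were not called, the same counts as adjusted over the list alone, with a median of -0.14 (camera adjusted p = 0.0271, and adjusted p = 0.217 with an estimated correlation). Hsd17b7 fell 2.85-fold, from 51.2 ± 0.675 to 17.98 ± 0.861 FPKM, and Ebp and Mvd fell 1.63-fold and 1.33-fold, while Idi1 rose 1.51-fold. The cholesterol list lost its call after rescaling to TPM (adjusted p = 0.116), scaling to the recovered totals (0.0984) or quantile normalization (0.469), and with a mean FPKM of at least 5 (0.152).

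All 27 cell cycle genes rose (27 adjusted over the list alone), with a median of 1.13 (camera adjusted p = 3.47e-18, and adjusted p = 0.137 with an estimated correlation), and 21 of them passed the submitters' thresholds. The mitotic kinesin Kif11 rose from 3.99 ± 0.204 to 14.1 ± 0.0606 FPKM, the centromere motor Cenpe from 0.586 ± 0.00391 to 3.54 ± 0.0141 FPKM and the topoisomerase Top2a from 9.18 ± 0.103 to 26.6 ± 0.147 FPKM. Of 16 p53 targets, 12 rose, Phlda3 fell and 3 were not called (13 and 1 adjusted over the list alone), with a median of 0.47 (camera adjusted p = 1.2e-05, and adjusted p = 0.148 with an estimated correlation). Pmaip1, which encodes the pro-death protein Noxa, rose from 2.15 ± 0.384 to 6.04 ± 0.272 FPKM, Trp53inp1 from 13.3 ± 0.661 to 28.4 ± 0.538 FPKM, Eda2r from 4.84 ± 0.316 to 10.7 ± 0.175 FPKM and Cdkn1a, the cell cycle inhibitor p21, from 24.3 ± 0.419 to 45.9 ± 1.19 FPKM.

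**Figure D2:**
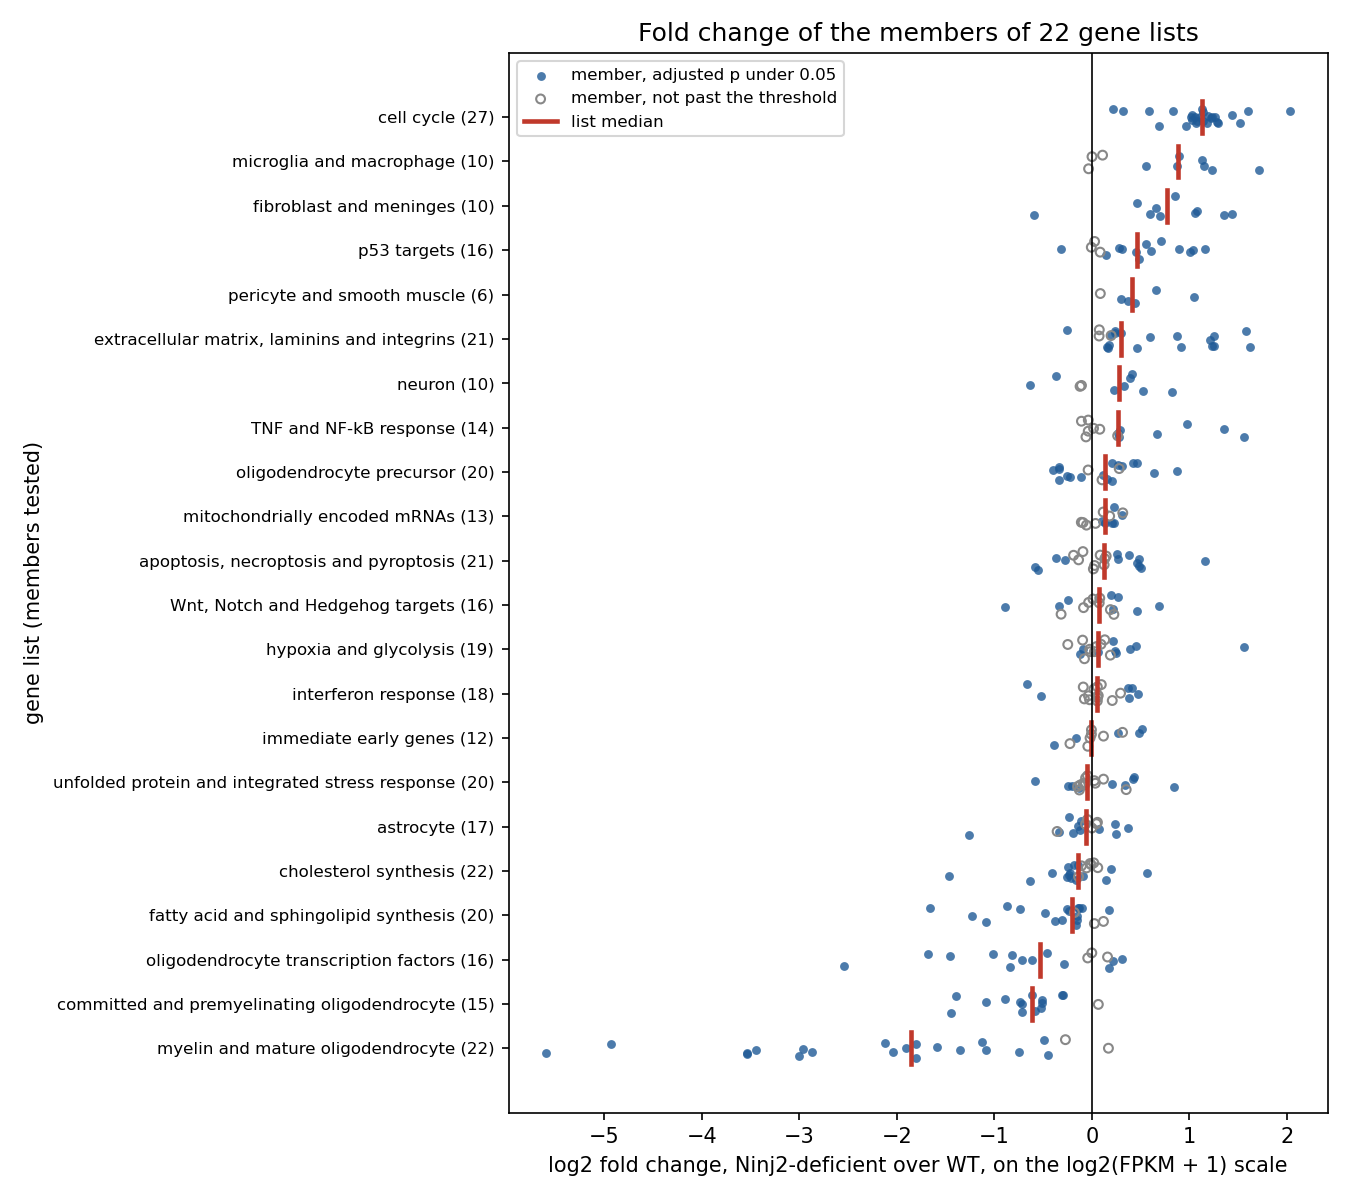
Each row is a gene list, with its number of tested members; points are members' log2 fold changes (Ninj2-deficient over WT, log2(FPKM + 1) scale), filled where the adjusted p was under 0.05, and red bars are list medians. The myelin list has the lowest median (-1.86) and the cell cycle list the highest (1.13).

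Extracellular matrix, laminin and integrin genes were higher. Of 21 tested, 17 rose, 1 fell and 3 were not called (18 and 1 adjusted over the list alone), with a median of 0.29 (camera adjusted p = 1.9e-08, and adjusted p = 0.148 with an estimated correlation). Nid1, a linker protein of basement membranes, rose from 5.15 ± 0.0142 to 17.9 ± 0.398 FPKM, Thbs1 from 0.984 ± 0.0618 to 4.95 ± 0.101 FPKM, and the basement membrane collagens Col4a1 and Col4a2 rose 2.52-fold and 2.60-fold. Of 14 genes of the TNF and NF-kB response, 7 rose and 7 were not called, as adjusted over the list alone, with a median of 0.26 (camera adjusted p = 0.0073, and adjusted p = 0.185 with an estimated correlation). The chemokine genes Ccl2, Ccl7 and Cxcl1 rose 3.52-fold, 3.72-fold and 1.90-fold and the adhesion molecule gene Icam1 2.49-fold, with Ccl2 at 12.3 ± 2.04 FPKM. The TNF list did not pass over genes with a mean FPKM of at least 5 (adjusted p = 0.109). Markers of fibroblasts and microglia rose beside these 2 lists, as given below.

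Also among the 12 largest rises were Spp1, the secreted protein osteopontin (11.9 ± 0.232 to 47.8 ± 0.611 FPKM), Mmp3, a matrix metalloproteinase (1.80 ± 0.131 to 7.32 ± 0.304 FPKM), Adm, the peptide adrenomedullin (1.31 ± 0.096 to 5.84 ± 0.726 FPKM), and Sarnp (5.81 ± 1.84 to 17.4 ± 2.40 FPKM). Mir7066 was listed at 0 in both WT libraries and rested on 5 fragments in the Ninj2-deficient group, so no fold is given. It lies within Ncan, from which its reads could not be told apart. Its call was lost in 6 alternatives.

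Markers of other cell types were also measured. The labels give no purity, and FPKM summed over different genes does not measure cell shares. Gfap, the astrocyte filament protein, was the most abundant nuclear-encoded mRNA over the 4 libraries, at 4452 ± 64.3 FPKM in WT and 4108 ± 26.8 FPKM in the Ninj2-deficient libraries. Summed over the astrocyte list, FPKM was 9407 in WT and 8567 in the Ninj2-deficient group, against 3987 and 939.7 for the myelin list. Of 17 astrocyte markers, 4 rose, 7 fell and 6 were not called, as adjusted over the list alone, with a median of -0.07, and the list did not pass (camera adjusted p = 0.299). S100b, also expressed by oligodendrocytes, fell from 56.1 ± 1.28 to 22.8 ± 2.09 FPKM and Gja1 from 62.4 ± 0.316 to 49.3 ± 0.726 FPKM, while Slc4a4 rose from 59.5 ± 0.598 to 70.9 ± 0.023 FPKM and Gli3 from 2.204 ± 0.114 to 3.14 ± 0.335 FPKM. Gli3 was not called with no filter (adjusted p = 0.0861), without WT library 1 (0.0644) or 2 (0.1), or without Ninj2-deficient library 1 (0.103).

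Of 10 fibroblast and meningeal markers 9 rose and Ptgds fell (9 and 1 adjusted over the list alone), with a median of 0.77 (camera adjusted p = 6.36e-05, and adjusted p = 0.148 with an estimated correlation). Col3a1 rose from 5.28 ± 0.203 to 15.97 ± 0.532 FPKM, Dcn from 1.12 ± 0.00869 to 4.41 ± 0.00806 FPKM, Lum from 0.424 ± 0.141 to 2.00 ± 0.185 FPKM and Col1a2 from 0.911 ± 0.00638 to 2.98 ± 0.00415 FPKM. Of 10 microglial and macrophage markers, 7 rose and 3 were not called, as adjusted over the list alone, with a median of 0.88 (camera adjusted p = 0.00237, and adjusted p = 0.185 with an estimated correlation). Lyz2 rose from 14.2 ± 1.67 to 48.7 ± 0.92 FPKM, C1qa from 0.834 ± 0.0429 to 3.34 ± 0.723 FPKM, Tyrobp from 0.487 ± 0.0971 to 2.33 ± 0.782 FPKM and C1qb from 0.593 ± 0.331 to 2.50 ± 0.966 FPKM, the last with an adjusted p of 0.0828 without WT library 1 and 0.064 without Ninj2-deficient library 2, and 0.0796 with no filter. Of 6 pericyte and smooth muscle markers, 5 rose, as adjusted over the list alone, with a median of 0.41 (camera adjusted p = 0.00596, and adjusted p = 0.185 with an estimated correlation). Acta2 rose 2.59-fold, Kcnj8 2.39-fold, Myl9 1.37-fold and Pdgfrb 1.36-fold. Pdgfrb lost its call without WT library 1 (adjusted p = 0.0564) or Ninj2-deficient library 1 (0.0533), and Kcnj8 without Ninj2-deficient library 2 (0.0586).

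Of 10 neuronal markers, 6 rose, 2 fell and 2 were not called, as adjusted over the list alone, and the list did not pass (median 0.28, camera adjusted p = 0.266). Gad2 rose 2.55-fold, Gad1 1.60-fold and Map2 1.34-fold, and Syt4 fell 1.68-fold. Among endothelial markers only Slco1a4 reached a mean FPKM of 1, at 1.27 ± 0.18 and 0.743 ± 0.11 FPKM, and it was not called (adjusted p = 0.0553). It was lower and called in 6 alternatives, among them voom (0.00119). Endothelial markers below the filter went both ways. Cdh5 had 16 and 16 fragments in the WT libraries and 42 and 53 in the Ninj2-deficient libraries. Emcn had 8 and 11 against 38 and 44, while Vwf had 215 and 245 against 179 and 191. No direction is given for endothelial markers. Of 3 Schwann and neural crest markers tested, Cdh19 rose 1.51-fold, a call that was lost in 6 alternatives including 3 of the 4 that left out a library (without WT library 1 and without each Ninj2-deficient library), and no red cell marker reached the filter.

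Other lists moved little or both ways. Of 19 hypoxia and glycolysis genes, 7 rose, 2 fell and 10 were not called (8 and 2 adjusted over the list alone), with a median of 0.07 (camera adjusted p = 0.0437, and adjusted p = 0.291 with an estimated correlation). Adm rose as above, Hk2 rose 1.47-fold, Vegfa 1.34-fold and Ldha 1.19-fold. That list's call was lost in 8 alternatives, among them those without WT library 1 (adjusted p = 0.102) and without Ninj2-deficient library 2 (0.0662). Of 13 mitochondrially encoded mRNAs, 6 rose and 7 were not called, as adjusted over the list alone, with a median of 0.13 (camera adjusted p = 0.0174, and adjusted p = 0.432 with an estimated correlation), but with the trend of fold change with GC content removed the median was -0.08 and the list passed in the other direction (adjusted p = 0.0384). Without WT library 2 the list was not called (adjusted p = 0.0571). The highest rises were those of mt-Cytb, 1.24-fold, and of mt-Nd4 and mt-Nd4l. The call of mt-Nd4l was lost in 7 alternatives, including 3 of the 4 that left out a library (adjusted p from 0.0619 to 0.143). With no filter, mt-Cytb (0.0691) and mt-Nd4 (0.0525) lost theirs.

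The interferon response (4 of 18 rose and 2 fell, median 0.06, camera adjusted p = 0.16), the apoptosis, necroptosis and pyroptosis list (8 of 21 rose and 4 fell, median 0.12, adjusted p = 0.16), the unfolded protein and integrated stress response (5 of 20 rose and 4 fell, median -0.06, adjusted p = 0.629), immediate early genes (3 of 12 rose and 2 fell, median -0.01, adjusted p = 0.433) and Wnt, Notch and Hedgehog targets (5 of 16 rose and 3 fell, median 0.08, adjusted p = 0.266) did not pass. Adjusted over the list alone, the counts of fallen genes were 5 for the apoptosis and the unfolded protein lists and 3 for the immediate early genes, with no other difference. The unfolded protein and immediate early lists had a median below 0 with a mean and a camera direction above 0. Among their called members, Slc7a11, a cystine transporter, rose 2.22-fold, Btg2 1.45-fold, Bcl2 1.64-fold, Nkd1 1.70-fold and Bst2 1.46-fold, and Hhip fell 3.80-fold, Mx2 2.17-fold, Vldlr 1.60-fold, Tradd 1.57-fold and the class I histocompatibility gene H2-D1 1.45-fold. Tradd lost its call without WT library 2 (adjusted p = 0.051).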

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

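Removal of the GC trend, voom, scaling to the recovered totals and the minimum of 50 fragments were chosen after seeing the data. Over all alternatives, 1720 values of named genes other than Ninj2 stayed on their side of the threshold, 45 lost their call, 6 gained one and 2 reversed. For gene lists the counts were 397, 31, 8 and 1. A change of direction was counted as reversed only where the value was called in the main setting or in the alternative. Ninj2 is given apart, below. The reversed ones all came with the GC trend removed: the median of the mitochondrially encoded list (-0.0778), mt-Nd4 (-0.0459) and mt-Nd2 (-0.0688); the correction itself lowers genes of low GC content. Called genes ran from 3685 to 4279 when each library was left out (higher genes 1498 to 1835), with fewer libraries in the fit; the lone library of an arm is then assumed to vary like the other group. The lowest count came without Ninj2-deficient library 2, and that without WT library 2 was 3767. Higher calls numbered 1548 with a mean FPKM of at least 5, where fewer genes were tested, and lower calls 1909 after rescaling to TPM and 2008 with recovered totals.

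Genes past the submitters' thresholds numbered 630 with a pseudocount of 0.1, 219 with a mean FPKM of at least 5, 564 after rescaling to TPM and 653 with voom. Of these, 290, 59, 303 and 313 were higher, and 197 were higher with a pseudocount of 0.5. A smaller pseudocount widens the folds of low genes. The list tests that passed fell from 14 to 7 with a mean FPKM of at least 5. There 4 lists lost their call and the microglia, pericyte and fibroblast lists had too few genes left to be tested. With an estimated correlation 0 passed by adjusted p. The simulated list's camera p there, 0.0192, was not adjusted. Without adjustment, camera gave 0.0125 for the myelin list and 0.00955 for the cell cycle list. For Ninj2, the log2 fold change was -0.45 with no filter (adjusted p = 0.0738) and -0.69 with voom (0.0621), neither called, and from -0.54 to -0.37 when libraries were left out; 84 and 57 fragments limit it. The numbers of replicates are shared between groups, but same-numbered libraries did not deviate together (r = 0.03 over genes), so the samples are not treated as paired; with a replicate block 5044 genes and 13 lists passed, the hypoxia list losing its call (adjusted p = 0.0515). The cause of other changes was not tested. Lists that did not pass in the report passed in some alternatives: with no filter the interferon (adjusted p = 0.0441) and neuron lists (0.0382), and with fry, which does not compare a list with other genes, these 2 (0.0127 and 0.0227) and the apoptosis (0.0415) and astrocyte lists (0.01). The submitters' test on counts was not run, and voom on the recovered fragments, added in its place, called 6696 genes.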

Other observations

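All tests in this part were chosen after the values had been seen, except that of the region around Ninj2. The gene families of the next paragraph were defined by symbol: 17 had at least 5 tested members, 10 passed camera, and none passed with an estimated correlation. The count that passed was 4 after rescaling to TPM, 3 after quantile normalization, 5 with recovered totals and 9 with the GC trend removed.

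Histone genes of the histone clusters went against the cell cycle genes. Of 22 tested, 15 fell, Hist1h1c rose and 6 were not called, with a median of -0.57 (camera adjusted p = 0.00511, and adjusted p = 0.286 with an estimated correlation) and between -0.50 and -0.61 under the scaling alternatives and with the GC trend removed, where the list passed each time. Hist1h4h fell from 7.35 ± 1.01 to 1.27 ± 0.0823 FPKM and Hist3h2ba from 92.6 ± 0.754 to 39.1 ± 3.06 FPKM (SD, n = 2). Kinesins divided. The mitotic Kif4 and Kif2c rose with log2 fold changes of 1.09 each, while Kif19a and the axonal transport kinesin Kif1a fell by 1.77 and 0.62, with 16 of 35 higher and 8 lower. Of 24 matrix metalloproteinases, their inhibitors and Adamts genes, 11 rose, 3 fell and 10 were not called (median 0.28, camera adjusted p = 0.00597, and adjusted p = 0.286 with an estimated correlation). Mmp2 rose from 3.49 ± 0.0982 to 8.51 ± 0.261 FPKM, while Adamts4 fell from 87.0 ± 0.531 to 21.1 ± 0.771 FPKM. Collagens divided too, with 12 of 23 higher, Col18a1 by 1.34, and 7 lower, Col20a1 by -1.48. Fibroblast markers, some of them collagens, rose beside these 2 families (list median 0.77, 9 of 10 higher). Proteasome genes (median -0.13, 20 of 37 lower) and complex I genes (median -0.15, 18 of 46 lower) were slightly lower, with camera adjusted p = 0.00511 and 0.00778, and adjusted p = 0.286 for both with an estimated correlation; after quantile normalization their adjusted p was 0.611 and 0.339. The median of ribosomal protein genes was -0.10 as deposited, 0.01 after rescaling to TPM and 0.08 after quantile normalization, so no direction is given.

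Myelin genes were lower and cell cycle genes higher. Fold changes of protein-coding genes fell with GC content (Spearman -0.34 across genes, which are not independent replicates; median 0.20 at up to 41.5% GC and -0.09 from 58.1% GC), but with that trend removed the medians were -1.88 for the myelin list and 1.17 for the cell cycle list, both still called, which argues against it as the whole cause. A loss of cells of the whole lineage as large as the fall of myelin genes would lower precursor genes alike, and their median was 0.14 (SD of members 0.35), although Sox10 fell and astrocytes also express some precursor genes, so a smaller loss stays open. A larger share of dividing cells was not tested and stays open. All 27 cell cycle genes rose, while histone genes of the clusters had a median of -0.57. How well these libraries capture histone mRNAs was not checked, so the histone values cannot decide it. A difference between cultures unrelated to genotype cannot be told apart from an effect of genotype, since libraries of a group may share a culture: chi-square per gene was at most 2.28 within groups and at least 47.3 between them.

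Connective tissue and microglial markers were higher. A smaller share of oligodendrocytes would raise markers of every other type alike. The astrocyte list had a median of -0.066 (SD of members 0.36) against 0.77 for the fibroblast list, which argues against it as the whole source of the rise. A smaller contribution stays open, since the astrocyte list also holds S100b, which oligodendrocytes express and which fell. A larger share of fibroblasts and of microglia may be a source, though counting risen markers cannot tell it from induction of the genes. Of 16 fibroblast markers with at least 20 fragments 87.5% were over 1.5 times higher, and of 16 microglial markers 81.2%, with median ratios of 2.66 and 3.44. Col3a1 (15.97 FPKM) and Lyz2 (48.7 FPKM) were the highest of those that rose this far, P2ry12 differed by less than its error, and Pdgfra, which the precursor list also holds, and Ptgds are expressed by the oligodendrocyte lineage. The cells were selected by immunopanning for O4. However, the astrocyte mRNA Gfap was the most abundant nuclear-encoded mRNA (4452 ± 64.3 FPKM in WT), so absence of either cell type cannot be assumed. Induction of these genes in other cells stays open.

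Ninj2 mRNA was lower but present. A complete loss of the mRNA is excluded, since the lowest Ninj2-deficient library held 27 Ninj2 fragments. The fall may follow that of other oligodendrocyte genes, but the values cannot decide it. On the log2(FPKM + 1) scale, 86.5% of the 37 tested myelin and premyelinating genes were at least as far down, against 7.07% of all tested genes. By the ratio of mean FPKM the shares were 73.0% and 5.12%. Both lists fell in these same data, so the shares show only that most of their genes fell at least as far as Ninj2. An allele that leaves an mRNA without its protein, or cells that kept the gene, were not tested, because the values are per gene and not per exon.

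Xist was 9.93 ± 0.531 FPKM in WT and 26.1 ± 0.502 FPKM in the Ninj2-deficient libraries (2.63-fold), while the Y-linked Ddx3y was 4.21 ± 0.57 and 4.79 ± 0.0474 FPKM and Kdm5d 2.58 ± 0.00813 and 2.19 ± 0.11 FPKM, neither called, nor was Uty (adjusted p = 0.727). The Y-linked Eif2s3y rose from 9.71 ± 0.313 to 11.1 ± 0.0595 FPKM (adjusted p = 0.0283). With the GC trend removed, Eif2s3y was not called and its direction turned (log2 fold change -0.09, adjusted p = 0.26), Uty (-0.31, adjusted p = 0.0346) and Kdm5d (-0.25, adjusted p = 0.0427) were called lower, and Xist stayed higher (1.17), so no direction is given for the Y-linked genes. Within 10 Mb of Ninj2, 4 of 157 tested genes passed the submitters' thresholds (Alox5, Mical3, Kcna1 and Tex52, all lower), against 352 of 12962 elsewhere (odds ratio 0.937, 95% interval 0.251 to 2.47, two-sided Fisher's exact test p = 1.0, and 0.833 and 0.725 for 5 and 20 Mb). Gapdh was listed at 2.04 ± 0.15 and 1.88 ± 0.00546 FPKM, and mt-Co2 at 35.3 ± 1.65 and 40.2 ± 2.72 FPKM beside mt-Co1 at 5561 ± 84.1 and 5968 ± 10.5 FPKM. Between the WT libraries, the difference also followed GC content (Spearman -0.29 across genes), and between the Ninj2-deficient libraries it was 0.05. Ndufa12 differed between the WT libraries (20.7 ± 14.0 FPKM, against 9.46 ± 0.817 FPKM in the Ninj2-deficient group).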
